A study of Mus musculus with 2 samples.

How the data were processed

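RNA from adult mouse ovary was measured by sequencing in 2 libraries, replicate 1 and replicate 2. Per the labels, both came from 8-week-old female littermates of the strain C57BL/6J, and the RNA was depleted of ribosomal RNA, selected for poly(A) tails and kept above 200 nucleotides. The libraries were stranded and read from both ends, 76 bases from each, per the labels. The labels call the libraries biological replicates, yet they cite the same donor record for both. Spread and tests therefore describe these 2 libraries, and some of that spread may be technical.

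Each library has a gene table and a transcript table on the mouse build mm10 with GENCODE M4 annotation, per the file headers and accompanying notes. The aligner and the quantifier are not given in the sources used here. The authors deposited expected counts, which are estimated read pairs per gene or transcript and need not be whole. The authors deposited TPM, which divides by effective length and has the same total in each library, spike-ins included. The authors deposited FPKM, which divides by effective length and by the number of fragments. The authors deposited, for each transcript, its percent of the gene's TPM. Posterior mean versions of the count and of TPM were also deposited. The series has 2 further tables on the older build mm9, one of splice junctions and one of contigs, which are stretches of the genome covered by reads. The authors' deposited junction table gives a count of reads per junction and a score for its significance. The authors' deposited contig table gives a signal level and a score per contig. How those tables were made is not given in the sources used here. Each junction name holds 2 read numbers whose sum was the count in every junction, and no source ties them to the replicates. It also holds a flag, A, whose meaning no source states. Coordinates on mm9 were never joined to those on mm10.

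Gene names came from GENCODE M21, which is on the same mm10 build (GRCm38). Of 43346 mouse gene identifiers, 42462 matched after their version was removed. Coordinates printed are those of M21. The other rows held 96 ERCC spike-ins, 1 phiX sequence and 26248 numeric identifiers. The spike-ins took 0.764% of the counts of replicate 1 and 0.986% of those of replicate 2, and the phiX and numeric rows took 0 counts. These rows were left out of library sizes and tests.

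Gene counts summed to 41124061 in replicate 1 and 34930860 in replicate 2. A gene with 0 counts allows up to 3 counts, which is 0.0730 CPM (the count over the library total, scaled) in replicate 1 and 0.0859 in replicate 2. Intervals, floors and standard errors of single ratios cover counting error only, since the reads carry no molecular identifiers. Levels are given as mean TPM ± SD over n = 2 libraries. The design holds 1 group, so no comparison between groups was possible. The comparison made was of replicate 2 with replicate 1.

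Expected counts were rounded to whole numbers. Genes with a mean count of at least 20 were kept, and libraries were scaled by TMM in edgeR 4.0.16 (R 4.3.3). The log2 ratio of replicate 2 over replicate 1 was computed with a prior count of 1. With 1 library on each side edgeR's quasi-likelihood test had no residual degrees of freedom. A two-sided exact binomial test per gene, with Benjamini-Hochberg adjustment at 0.05, was used in its place. It compares the reads of these 2 libraries, not conditions. The biological coefficient of variation is the square root of edgeR's common dispersion. DESeq2 1.42.0 gave alternative size factors and dispersions. Other steps used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

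The study design, 25 gene lists, the tests, the rule for named genes and most alternatives were fixed before the data were examined. The lists held 361 entries, of which 11 matched no identifier, and 323 different genes were measured. A list's median level was set against 10000 random lists of protein-coding genes of the same size, and called above the 97.5th percentile. Those were drawn from all protein-coding genes, detected or not, with no matching on expression. A list's median log2 ratio was set against 10000 random lists matched on mean expression in 20 bins, and called outside the central 95%. Both are descriptions of these libraries. Lists share genes: the luteal cell and steroid hormone synthesis lists have 6 in common. Transcript shares were computed for genes with at least 2 annotated transcripts and a mean count of at least 100.

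The genes named were chosen by rule. They are the 10 nuclear protein-coding genes with the highest mean TPM, and the 3 highest members of each list (all members of a list of up to 6). They are also Fshr, Lhcgr, Cyp19a1, Cyp17a1, Star, Foxl2, Amh, Zp3, Gdf9, Ovgp1, Pgr and Ptgs2 whatever their level. To these come the 5 protein-coding genes with the largest and the 5 with the smallest log2 ratio at a mean count of at least 100, and the 5 most abundant lincRNA or antisense genes. The rule also takes the 5 list members with a mean count of at least 200 and the lowest share for their main transcript. Finally it takes, in each list called different between libraries, the 3 members with the largest absolute log2 ratio. Genes outside the rule are marked as chosen after their values were seen. Some genes that the rule takes are not reported here.

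The procedures were tested on simulated data. For the comparison of replicate 2 with replicate 1 over 15939 genes, counts were drawn with 200 genes changed 2-fold. The binomial test called 92.0% of the changed genes and 9 unchanged ones. Those counts were drawn with counting noise only. The real libraries spread further, so these rates hold for counting noise and not for spread between replicates. Among 100 simulated lists with no shift, 2 were called. Their genes varied independently, so this rate does not cover lists whose members vary together or share reads. Simulated coefficients of variation of 0.1, 0.2 and 0.3 were estimated at 0.100, 0.200 and 0.296.

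Alternatives covered thresholds, filters, units, posterior mean estimates, DESeq2 size factors and each library alone. Scaling to the spike-in total, removing the trend with GC content and rescaling to nuclear protein-coding genes were added after seeing the data. GC content and length were those of each gene's longest M21 transcript, and 99.4% of the filtered genes had a value.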

Results

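The series measured polyadenylated RNA in the ovary of 8-week-old mice, in 2 libraries of 1 group. Replicate 1 held 41124061 gene counts and replicate 2 held 34930860. The 10 genes with the most counts took 4.49% of the total in replicate 1 (95% Wilson interval 4.49% to 4.50%) and 4.29% in replicate 2 (4.28% to 4.30%). The design asks which genes the ovary expresses, and how far its 2 replicates differ. The libraries differed beyond counting noise, with a chi-square of 75.0 per degree of freedom over 15939 genes, which does not tell animals from library preparations.

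In both libraries, 14235 genes reached a TPM of 1. Of these 13312 were protein-coding, 62.0% of the 21474 annotated. Among the most abundant nuclear protein-coding genes, Inha, the inhibin alpha subunit made by granulosa cells, stood at 6837 ± 789.9 TPM (SD, n = 2). Inha lies on chromosome 1 at 75507077 to 75510366 of mm10. Igfbp7, a secreted binding protein of insulin-like growth factors, stood at 8015 ± 4324 TPM, with 4958 in replicate 1 and 11073 in replicate 2. The cytoskeletal actin Actb stood at 7479.7 ± 4.58 TPM and Tpt1 at 4396 ± 1628. Ribosomal protein genes among the most abundant included Rplp1 (12747 ± 4289 TPM), Rps12 (7335 ± 618), Rpl13 (5161 ± 383), Rps21 (5055 ± 275) and Rps2 (4263 ± 98.5). Ribosomal protein genes have many processed copies, so their split of reads is uncertain.

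Genes of the oocyte were detected at moderate levels, with 23 of 28 at a TPM of 1 or more in both libraries. Tle6, a part of the maternal complex of the egg, stood at 185 ± 10.2 TPM (SD, n = 2). Zp3, a protein of the egg coat, stood at 169 ± 24.8 TPM. Gdf9, a growth factor secreted by the oocyte, stood at 95.5 ± 16.3 TPM. Zp3 lies on chromosome 5 at 135980099 to 135988624 and Gdf9 on chromosome 11 at 53431023 to 53437904. The list's median of 11.5 TPM lay at the 92.0th percentile of random lists and was not called.

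All 16 genes of the granulosa cell list were detected, with a median of 66.5 TPM that lay above all random lists drawn. Amh, the anti-Müllerian hormone of growing follicles, stood at 317 ± 24.0 TPM (SD, n = 2) and the inhibin subunit gene Inhbb at 308 ± 32.8. The transcription factor gene Foxl2 (chromosome 9, 98955288 to 98958543) stood at 49.8 ± 4.08 TPM. Fshr, the receptor of follicle-stimulating hormone, stood at 21.5 ± 3.97 TPM. Cyp19a1, the aromatase that makes estrogen, stood at 8.54 ± 2.57 TPM.

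Steroid-making genes were among the higher lists. The theca and interstitial cell list had a median of 153 TPM, the steroid hormone synthesis list 76.2 and the luteal cell list 73.7, and all were called above random lists. Hsd3b1, which makes progesterone from pregnenolone, stood at 1497 ± 272 TPM (SD, n = 2). Cyp11a1, which cleaves the cholesterol side chain, stood at 1334 ± 11.9 TPM. The lipoprotein receptor gene Scarb1 reached 985 ± 209.5 TPM and the Leydig and theca cell hormone gene Insl3 636 ± 72.5. Cyp17a1, needed for androgen synthesis, stood at 219 ± 32.7 TPM and Star, which carries cholesterol into mitochondria, at 108 ± 20.9. Cyp11a1 lies on chromosome 9 at 58006411 to 58027023 and Star on chromosome 8 at 25806555 to 25815982. Cholesterol synthesis and uptake genes had a median of 34.1 TPM, also called. Among them Dhcr7 stood at 270.4 ± 88.9 TPM and Fdps at 119.95 ± 27.1.

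Hormone receptor genes were all detected, with a median of 24.0 TPM at the 97.6th percentile. Amhr2, the receptor of the anti-Müllerian hormone, stood at 147 ± 12.2 TPM (SD, n = 2), Lhcgr, the receptor of luteinizing hormone, at 121 ± 41.9, and the estrogen receptor gene Esr1 at 91.7 ± 9.61. Gonadal transcription factor genes had a median of 83.1 TPM, above all random lists drawn. Nr5a1 stood at 316 ± 5.25 TPM, Gata4 at 251 ± 24.6 and Wt1 at 205 ± 8.11. Genes induced at ovulation had a median of only 3.19 TPM and were not called. Within that list Cebpb stood at 1131 ± 225 TPM, Adamts1, a matrix protease, at 46.5 ± 7.69, and the progesterone receptor gene Pgr at 46.0 ± 31.2. Ptgs2, the inducible prostaglandin synthase, stood at 0.775 ± 0.148 TPM.

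Marker lists of several other cell types had high levels, which does not measure how much of each cell type was present. The stroma and matrix list had the second highest median, 215 TPM, led by Sparc (3836 ± 768 TPM, SD, n = 2), Mgp (1580.3 ± 62.2) and Fbln1 (347 ± 31.8). Smooth muscle genes had a median of 130.3 TPM, with the contractile actin Acta2 at 2152 ± 239 TPM, Tagln at 1043 ± 34.7 and Actg2 at 424 ± 22.5. Adipocyte genes had a median of 136 TPM, with Cfd, the adipsin made by fat cells, at 2427 ± 489 TPM, Car3 at 843 ± 85.8 and Plin4 at 198 ± 2.41. Endothelial genes had a median of 56.3 TPM, with Egfl7 at 333 ± 45.2 TPM, Sox17 at 285 ± 58.0 and Sox18 at 200.2 ± 9.11. Surface epithelium genes had a median of 48.5 TPM, with the keratin genes Krt19 at 358 ± 84.0 TPM, Krt8 at 160.3 ± 29.1 and Krt18 at 115 ± 3.32. Macrophage genes had a median of 35.3 TPM, with C1qc at 183 ± 9.36 TPM, Lyz2 at 173 ± 56.2 and C1qb at 139.7 ± 25.7. These 6 lists were called above random lists.

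The oviduct list had a median of 13.7 TPM and was not called, yet Ovgp1, a glycoprotein secreted by oviduct epithelium, stood at 577 ± 70.0 TPM (SD, n = 2). Foxj1, a regulator of motile cilia, stood at 125 ± 17.9 TPM and Tmem212 at 75.7 ± 1.49. Lymphocyte genes had a median of 0.922 TPM, with the immunoglobulin gene Ighm at 35.2 ± 16.7 TPM, Lck at 3.52 ± 0.658 and Nkg7 at 3.32 ± 0.354. Genes of other organs had a median of 0.427 TPM. The highest were the myelin gene Mbp (17.4 ± 2.18 TPM), the serum albumin gene Alb (23.4 in replicate 1 and 6.62 in replicate 2) and the thyroid hormone carrier gene Ttr (4.49 ± 4.26). Xist, expressed from the inactive X chromosome, stood at 36.7 ± 11.4 TPM. The Y-linked genes Uty, Sry, Ddx3y and Eif2s3y had 0 counts in both libraries, which allows up to 3 counts in each, and Kdm5d had 1 count in replicate 1.

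Proliferation genes had a median of 18.7 TPM at the 96.9th percentile and were not called. Pcna stood at 85.4 ± 15.6 TPM (SD, n = 2), Ccna2 at 76.8 ± 19.6 and Mcm7 at 54.6 ± 12.7. Erythroid genes had a median of 49.8 TPM and were called. The alpha globin genes Hba-a2 and Hba-a1 stood at 714 ± 282 and 528 ± 347 TPM, and the beta globin gene Hbb-bs at 375 ± 178. In replicate 1 alone the erythroid list, at 36.7 TPM, was no longer called and the proliferation list, at 22.8 TPM, was. Immediate early genes had a median of 52.7 TPM, with Jun at 140.3 ± 33.7 TPM, Egr1 at 92.9 ± 0.311 and Junb at 91.9 ± 17.0. Heat shock genes had a median of 68.3 TPM, with Hspa8 at 2744 ± 409 TPM, Hspb1 at 488 ± 38.9 and Hspa1b, which has a near-identical copy and is uncertain, at 134 ± 16.7. Both of these lists were called.

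RNAs without a poly(A) tail remained in these libraries. The list's median was 53.4 TPM and was called. Rn7sk, a small nuclear RNA that restrains transcription elongation, had the highest level in the list at 27006 ± 2985 TPM (SD, n = 2). The mitochondrial RNA processing gene Rmrp stood at 6213 ± 517 TPM. Rn7s1 and Rn7s2 encode the same signal recognition RNA and had identical values, 5675 ± 26.8 TPM each, so their split is not informative. Rn7sk, Rmrp and Rn7s1 have 331, 271 and 300 bases, near the implied mean fragment lengths of 228 and 206 bases. TPM divides by effective length and is unstable for them. Rmrp had 6579 TPM in replicate 1 and 5848 in replicate 2, while its log2 ratio of scaled counts was 0.45. Messenger RNAs of the mitochondrial genome had the highest median of all lists, 365 TPM. mt-Co1 stood at 4801 ± 1977 TPM, mt-Co3 at 3557 ± 1972 and mt-Atp6 at 754 ± 434. Among genes annotated as lincRNA or antisense, the most abundant were Gm42418 (1754 ± 55.2 TPM), Gm10076 (1265 ± 621), Gm26917 (1091 ± 527), Meg3 (489 ± 90.3) and 2900097C17Rik (323 ± 144). Gm26917 and Gm42418 are neighbours on the plus strand of chromosome 17 (39843013 to 39846341 and 39846958 to 39848788), with 69.1% and 60.2% GC. Whether their reads, or those of the 384-base Gm10076, come from other RNA was not tested. In all, 18 of the 25 lists lay above random lists in level. Those random lists drew on all protein-coding genes, of which 62.0% were detected in both libraries. A list of expressed genes is thus easily called, and the call does not measure enrichment of a cell type.

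**Figure D1:**
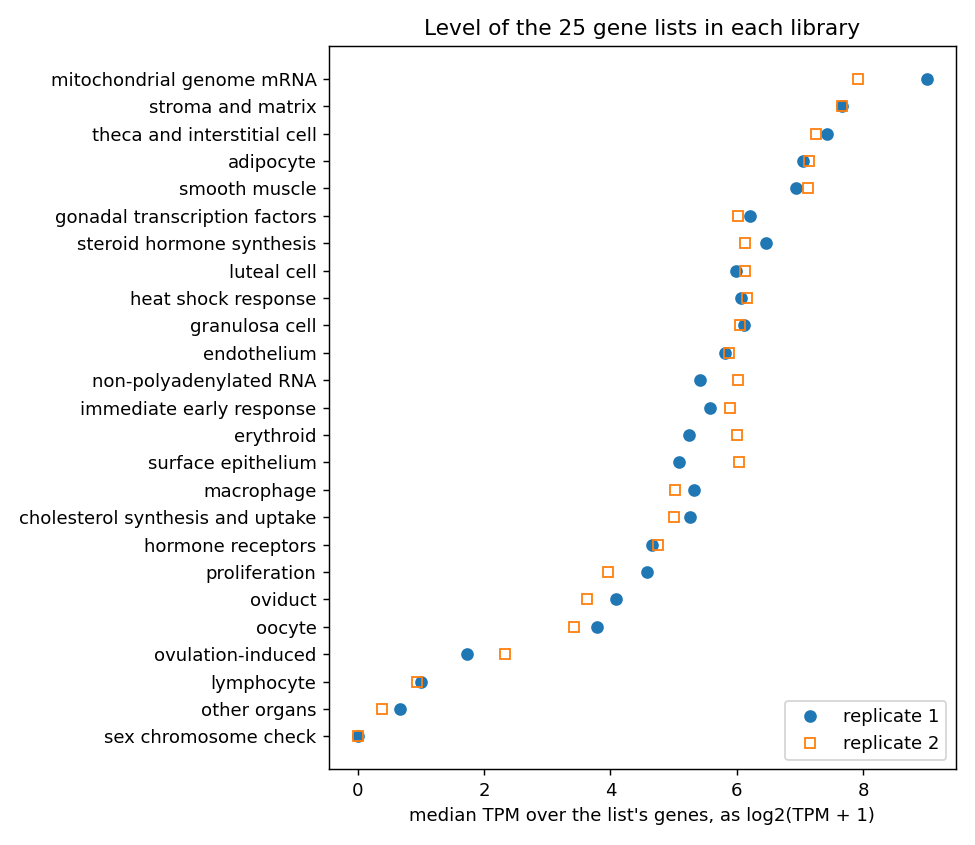
Median TPM of each of the 25 gene lists, as log2(TPM + 1) on the x axis, with a filled circle for replicate 1 and an open square for replicate 2. Mitochondrial mRNA had the highest median, with 515 TPM in replicate 1 and 242 in replicate 2, which are the uncertain values of mt-Nd4l and mt-Atp8 (539.5 and 301 without these genes), and the genes of the sex chromosome check had the lowest.

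The second comparison was between the replicates. Across 14720 genes with a mean TPM of at least 1, log2(TPM + 1) had a Pearson r of 0.972 and a Spearman rho of 0.973; genes are not independent replicates. The median absolute log2 ratio was 0.23, and the biological coefficient of variation was 0.203, against 0.0917 as the median of DESeq2's gene-wise estimates. The spike-ins, which are synthetic RNAs, also spread. Relative to their own total, the 41 with a mean count of at least 20 had log2 ratios with an SD of 0.34, counting noise included. ERCC-00017 (48716 and 71515 counts) differed by 0.42 and ERCC-00018 (17418 and 14997 counts) by -0.35. Some spread between the libraries is thus technical, and its share in the spread of the genes was not tested. By the exact binomial test, genes differing beyond counting noise numbered 8947 of 15939 (56.1%), 4646 higher and 4301 lower in replicate 2, and 4763 with Bonferroni adjustment. The genes differing over 2-fold numbered 636, 364 higher and 272 lower in replicate 2. At a mean count of at least 100 they numbered 298, 213 higher and 85 lower, with no filter 3346, 1861 higher and 1485 lower, and on log2(TPM + 1) 410. Scaled to the spike-in total, every log2 ratio was lower by 0.43 and the median of all genes moved to -0.44. On that scale 123 genes were over 2-fold higher and 1102 lower, and 1142 were higher and 11431 lower beyond counting noise. The directions that follow are relative to the other genes, and any ratio or list median between 0 and 0.43 turned to lower on the spike-in scale.

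**Figure D2:**
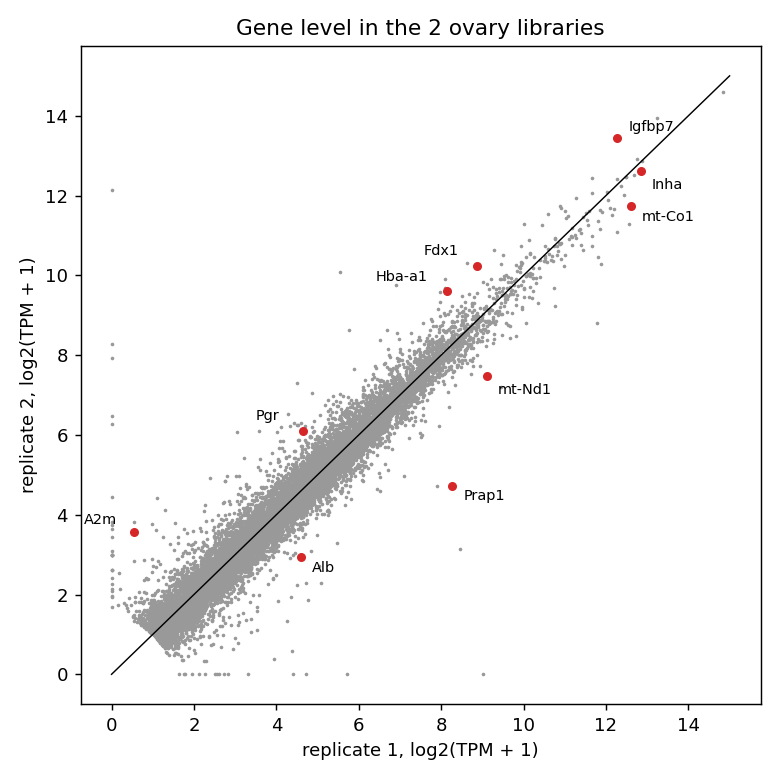
Level of each gene with a mean TPM of at least 1, as log2(TPM + 1), in replicate 1 (x axis) and replicate 2 (y axis), with the line of equality and 10 named genes in red. Most genes lie along the line (Pearson r 0.972), with Pgr and A2m above it and Prap1, Alb and mt-Nd1 below it.

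The median log2 ratio of 9 lists lay outside that of random lists. Mitochondrial messenger RNA was lower in replicate 2, with a median of -1.10. Of 12 members with enough counts, 10 were lower past the exact binomial test and none higher, both over all genes tested and adjusted over the list alone. mt-Nd1 differed by -1.56 (counting SE 0.02), mt-Cytb by -1.28, mt-Co1 by -0.81 and mt-Co3 by -1.11. mt-Nd4l had 1063 expected counts in replicate 1 and 0 in replicate 2, but posterior mean counts of 1151 and 119, so the 0 is an uncertain assignment of reads and gives no fold. With 3 counts in its place the list's median stayed at -1.10. Neighbouring mitochondrial genes and nuclear copies make the single estimates uncertain. mt-Nd3 was listed at 0 in both libraries.

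Proliferation genes were lower in replicate 2, with a median log2 ratio of -0.48, below all random lists drawn. Past the exact binomial test 18 of 20 were lower and 1 was higher, or 18 and 2 adjusted over the list alone. Cdc20, an activator of the anaphase-promoting complex, differed by -0.80, the replication helicase gene Mcm5 by -0.71 and Bub1, on 67 and 33 counts, by -0.71. Ccna2 was the exception past the test over all genes, at 0.20.

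Steroid hormone synthesis genes were lower as a list, with a median of -0.35, 10 of 17 lower and 4 higher past the exact binomial test, and the same counts adjusted over the list alone. The mean of -0.13 lay inside random lists. Members went both ways. Hsd3b1 differed by -0.45, Star by -0.35 and Cyp19a1 by -0.58, and Cyp11b1, on 65 and 30 counts, by -0.80. Fdx1, the electron carrier of steroid-making cytochromes, was higher by 1.45 and Hsd17b7 by 1.08. The theca and interstitial cell list had a median of -0.19, with 9 of 14 lower and 3 higher, or 10 and 3 adjusted over the list alone. Aldh1a1 differed by -0.45 and Lhcgr by 0.77. The granulosa cell list had a median of -0.14, with 9 of 16 lower and 5 higher by both adjustments. Nr5a2 differed by -0.65 and the gap junction gene Gja1 by -0.47. On log2(TPM + 1) the granulosa median was -0.08 and lay inside random lists.

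Erythroid genes were higher in replicate 2, with all 5 members that had enough counts past the exact binomial test by both adjustments and a median of 0.91. Hba-a1 was higher by 1.61, Hba-a2 by 0.96 and Hbb-bs by 0.91. Near-identical globin copies share reads, and the 6 globin genes with counts, summed, were higher by 1.10. Surface epithelium genes had a median of 0.38 and 9 of 10 members higher past the test by both adjustments, but the median turned to -0.059 under spike-in scaling. Epcam, an adhesion molecule of epithelia, was higher by 0.93, Krt7 by 0.92 and the stem cell marker gene Lgr5 by 0.90. Immediate early genes had a median of 0.28, which turned to -0.16 under spike-in scaling, with 10 of 12 higher and none lower by both adjustments. Fosb was higher by 0.65, Ier3 by 0.57 and Jun by 0.54. The list of RNAs without a poly(A) tail had a median of 0.43, which turned to -0.0036 under spike-in scaling and was 0.25 with the trend with GC content removed, with 9 of 12 higher and 1 lower by both adjustments. The histone genes Hist1h2ab, Hist1h2ae and Hist1h3b were higher by 0.96, 0.83 and 0.81, and have near-identical copies. On log2(TPM + 1) the immediate early and the tail-less lists lay inside random lists, with medians of 0.18 and 0.05.

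**Figure D3:**
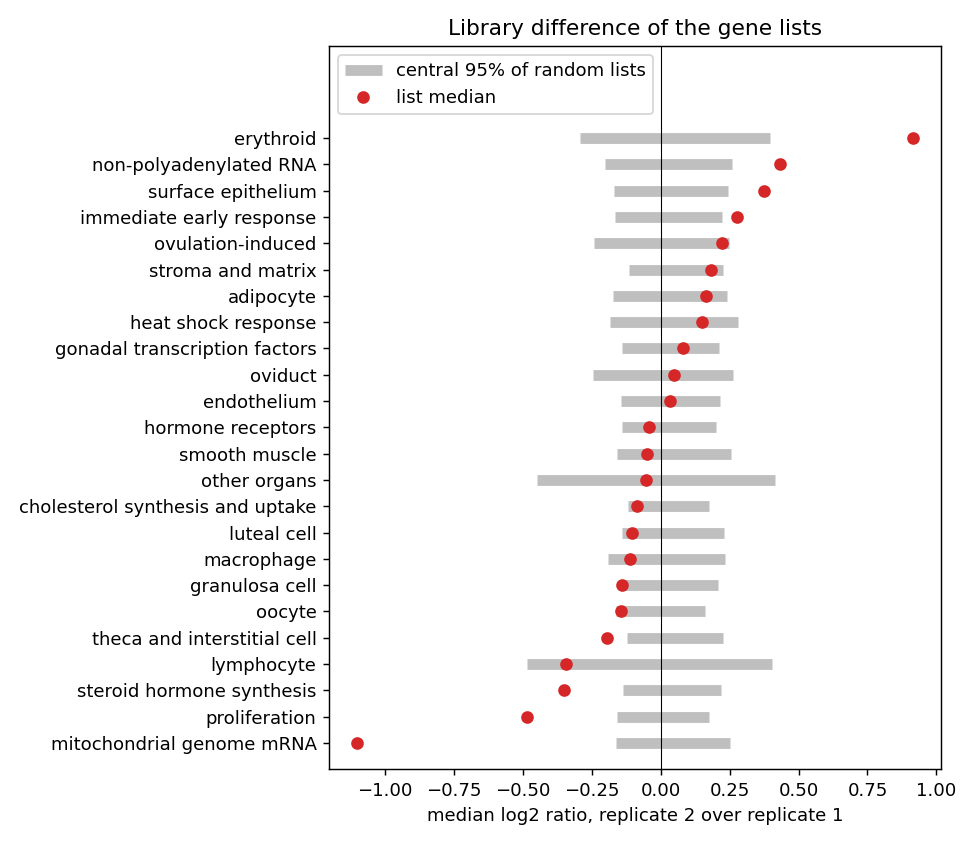
Median log2 ratio of replicate 2 over replicate 1 for the gene lists with enough measured members (x axis, red points), with grey bars for the central 95% of 10000 random lists matched on expression. Mitochondrial mRNA (-1.10) and proliferation (-0.48) lie left of their bars and the erythroid list (0.91) right of its bar.

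The other lists lay inside random lists, and the counts given are of members past the exact binomial test. Oocyte genes had a median of -0.14 with 5 higher and 11 lower of 26, and luteal cell genes -0.10 with 6 and 6 of 12. Cholesterol synthesis and uptake had -0.09 with 6 higher and 10 lower of 23, hormone receptors -0.04 with 6 and 4 of 15, and gonadal transcription factors 0.08 with 7 and 2 of 15. Genes induced at ovulation had 0.22 with 8 higher and 0 lower of 13, or 8 and 1 adjusted over the list alone. That list, not called by its median, was called by its mean of 0.37. Oviduct genes had 0.05 with 1 higher and 3 lower of 11, stroma and matrix 0.18 with 9 and 5 of 14, and smooth muscle -0.05 with 3 and 4 of 10. Endothelium had 0.03 with 6 higher and 4 lower of 14, macrophage genes -0.11 with 0 and 5 of 13, and lymphocyte genes -0.34 with 0 and 2 of 7. Adipocyte genes had 0.16 with 7 higher and 2 lower of 11, heat shock genes 0.15 with 5 and 3 of 9, and other organs -0.05 with 1 and 2 of 7. Apart from the ovulation list, adjusting over the list alone gave the same counts. The mean had the opposite sign to the median for luteal cells (0.12), hormone receptors (0.15) and oviduct (-0.03). The sex chromosome check had only Xist with enough counts, at 0.69. With the GC trend removed the heat shock median was 0.0045, and with no filter on counts the lymphocyte median was 0.0054. On log2(TPM + 1) the hormone receptor and oviduct medians turned to 0.11 and -0.15, and the lymphocyte median was -0.12. On that scale the oocyte median of -0.19 and the ovulation median of 0.19 lay outside random lists. Within the ovulation list Pgr was higher in replicate 2 by 1.54 (counting SE 0.04), with 24.0 and 68.0 TPM.

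Single genes differed further. A2m, a protease inhibitor of plasma, had 60 counts in replicate 1 and 1200 in replicate 2, a log2 ratio of 4.60 (counting SE 0.19). Sprr1a, a cornified envelope protein gene, was higher in replicate 2 by 3.66 (SE 0.37), Npcd by 3.44 (SE 0.25) and the histone gene Hist1h2ad by 2.89 (SE 0.28). Gm20425 had 0 expected counts in replicate 1 and 688 in replicate 2, and posterior mean counts of 23.8 and 692. It spans 103190208 to 103230307 of chromosome 9 and overlaps Trf on the same strand, so its reads are uncertain and no fold is given. Prap1, on chromosome 7 at 140093395 to 140097200, had 3575 counts in replicate 1 and 260.0 in replicate 2, a log2 ratio of -3.48 (SE 0.09). Hmga1b differed by -3.45 (SE 0.33), Aspg by -2.66 (SE 0.10) and Mmel1, a metalloprotease gene, by -2.55 (SE 0.12). The expected counts of Hmga1b (279.55 and 19.5), Npcd (37.97 and 343.93) and Hist1h2ad (29.69 and 186.93) were not whole. Some of their reads were therefore split in estimation, and their ratios are less certain than the counting SEs. Alb differed by -1.77 (SE 0.09) and Ttr by -2.25 (SE 0.26). All of these passed the exact binomial test between the libraries.

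At the level of transcripts, 9449 genes had at least 2 annotated transcripts and a mean count of at least 100. The genes with a dominant transcript numbered 3194 (33.8%), where a transcript held at least 80% of the gene's TPM in both libraries, and at 50% this held for 6609. The most abundant transcript was the same in both libraries for 8104 genes (85.8%). Cyp11a1 and Ovgp1 each had a main transcript with 96.8% and 97.4% of the gene's TPM, and Zp3 one with 99.9%. Other markers had no dominant transcript by this rule. The main transcript of Pgr held 41.8%, and that of Nr5a2 held 45.5% in replicate 1 and 92.9% in replicate 2. The list members with the lowest share for their main transcript were Fn1 (25.5 ± 10.4% SD, n = 2), Msmo1 (26.7 ± 23.5%), Egfl7 (27.1 ± 1.92%), Tle6 (29.5 ± 5.25%) and the prolactin receptor gene Prlr (32.5 ± 8.36%). For Msmo1, a sterol oxidase gene, the share was 10.1% in replicate 1 and 43.3% in replicate 2.

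The authors' deposited table on mm9 listed 438382 splice junctions with 27636523 reads. Junctions with the flag A set made up 36.2% of the table and held 95.6% of the reads, with a median of 26 reads, against 1 read for the others. In 83.0% of the junctions with the flag set both read numbers were above 0, against 13.4% of the others. The length, chromosome and strand of an M21 intron were matched by 99.8% of junctions with the flag set and 49.6% of the others, a comparison of lengths and not of positions. At 10 reads or more 116810 junctions remained, and at a score of at most 0.01 107868. The authors' contig table, also on mm9, listed 667197 contigs that covered 209 Mb over both strands, with a median length of 201 bases. At a score of at most 0.01 the contigs numbered 236428, with a median length of 437 bases against 124 for the rest, and 335041 contigs had at least 200 bases.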

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

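The tests of nuclear copies, transcript length and granulosa cells were chosen after the results were seen, and removal of the GC trend was added after seeing the data. ERCC spike-ins, synthetic RNAs used only for an alternative scaling, gave a signal above the limit of a count of 0. They took 0.764% of counts in replicate 1 (95% Wilson interval 0.762% to 0.767%) and 0.986% in replicate 2 (0.983% to 0.989%). Of 96 spike-ins, 57 had counts in both libraries. How much was added to each is not given in the sources used here.

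Mitochondrial messenger RNA was lower in replicate 2, and no biological explanation was tested, since the design has 1 group. The tables argue against GC content: with its trend removed the list's median log2 ratio was -1.09, outside random lists. For the genes summed, the tables also argue against reads moved to 7 nuclear pseudogene copies. Mitochondrial genes and these copies, summed, differed by -0.89. Only copies with a share of at least 0.25 of 31-base stretches were counted. In replicate 1 mt-Co1 held 241337 of the 410269 mitochondrial counts, so the sum says little about single smaller genes. The copies themselves were lower, by -0.75. Differences in tissue handling, in library preparation and in the animals stay open, untested.

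Proliferation genes were lower in replicate 2. No trend with GC content or length toward lower ratios was of that size. The lowest median among 20 bins of protein-coding genes was -0.060 by GC content and -0.042 by length. Removing the small GC trend left a median of -0.45 for the list, outside random lists. A smaller share of granulosa cells, which divide in growing follicles, would lower granulosa markers about as far. That holds only if the markers come from those cells alone, which was not tested. The granulosa list was itself lower, with a median of -0.14. It lay 0.34 above proliferation genes, at the 99.6th percentile of random pairs of lists (0.29 and the 99.4th with the GC trend removed). Proliferation genes already lay below all random lists, so this percentile is not independent support. The granulosa list fell less than proliferation genes. With bounds set after these values were seen, this does not decide how far fewer granulosa cells contributed. A different mix of follicle stages between animals may contribute, untested.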

How the results depend on the processing

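Spike-in scaling, removal of the GC trend and rescaling to nuclear protein-coding genes were added after seeing the data. Alone, the libraries had 14615 to 14752 detected genes and 3714 to 3791 genes with a dominant transcript; genes detected in both libraries ranged from 10416 (TPM of at least 5) to 16599 (at least 10 counts). The gene-level agreement of the libraries, a Pearson r of 0.972, was 0.960 with a pseudocount of 0.1, 0.991 with no filter, 0.986 on log2 CPM, 0.946 on posterior mean TPM and 0.980 on nuclear protein-coding genes. Bonferroni adjustment left 4763 genes differing beyond counting noise. The genes differing over 2-fold numbered 3346 with no filter, 298 at a mean count of at least 100 (213 higher and 85 lower in replicate 2), 410 on log2(TPM + 1) and 1225 under spike-in scaling; the stricter and looser filters test fewer and more genes. The coefficient of variation was 0.0917 as DESeq2's gene-wise median, a median over genes and not a pooled value. A threshold of 50% gave 6609 genes with a dominant transcript. A score of at most 0.01 left 107868 junctions and 236428 contigs; 10 reads left 116810 junctions and 200 bases left 335041 contigs. Spike-in scaling, a constant shift, turned every positive list median to negative except that of the erythroid list, which was 0.48 on that scale. Among the lists called different between libraries it turned surface epithelium (-0.059), immediate early (-0.16) and tail-less RNA (-0.0036). Among lists not called it turned ovulation (-0.21), stroma and matrix (-0.25), adipocyte (-0.27) and heat shock (-0.29). It also turned gonadal transcription factors (-0.36), oviduct (-0.39) and endothelium (-0.40).

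The 9 lists called different between libraries were the same with DESeq2 size factors, no filter and the GC trend removed. On log2(TPM + 1) 6 of them were called, and with means 8. Both settings also called genes induced at ovulation, and log2(TPM + 1) called oocyte genes. Of the 18 lists called high, 17 were called in replicate 1 alone and 18 in replicate 2 alone; the mean of log2(TPM + 1) called all 18 and also the oviduct and proliferation lists. The causes were not tested. Depth limits genes near 3 counts, such as the Y-linked genes, and a group of 2 limits every SD.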

Other observations

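The liver genes other than Alb and Ttr were listed after those were seen and before their own values were. Some list members outside the naming rule, chosen after their values were seen, differed between libraries. Edn2, a vasoconstrictor peptide gene induced at ovulation, was higher in replicate 2 by 2.42, with 5.95 and 30.6 TPM. The oocyte genes Npm2 and Zar1 were higher by 1.02 and 0.83, while Nobox differed by -0.71 and Zp1 by -0.45. Among matrix genes the collagen gene Col5a1 was higher by 0.65 and Dcn differed by -0.46. Sfrp4 and Ptgfr of the luteal list were higher by 0.53 and 0.72, and Gata6 by 0.70. All of these passed the exact binomial test between the libraries.

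Alb and Ttr were lower in replicate 2, and a candidate source is liver RNA in replicate 1, a hypothesis. Of 14 other liver genes measured, 11 had enough counts, and 8 of these were lower by over 1 on the log2 scale. In all, 10 of the 11 were lower, with Ahsg just short of that cut at -0.997. The median of the 11 was -1.40. The bound for the hypothesis, 10 genes, was set over all 14 and did not allow for the 3 with too few counts, and the bound against it was under 6. The value lay between, so the hypothesis stays open. The highest were Trf (456 ± 211 TPM, SD, n = 2) and Apoa1 (52.3 ± 12.9 TPM), which differed by 0.52 and -0.45. Apoa2 differed by -2.58 and Apoc3 by -1.36. Of all 16 liver genes, 9 reached a TPM of 1 in replicate 2 too. The 2 that stand in a gene list are Alb and Ttr, in the list of other organs.

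The 4 globin genes of the erythroid list had a median log2 ratio of 0.94, and 0.93 with the GC trend removed. Very short genes had unstable TPM. Gm10774, a pseudogene of 204 bases chosen after its values were seen, had 59.6 counts and a TPM of 0 in replicate 1, and 708 counts and a TPM of 4512 in replicate 2. Its effective length was listed at 0 and 6.38 bases. The implied mean fragment lengths were 228 bases in replicate 1 and 206 in replicate 2. mt-Atp8, also of 204 bases, had 64 counts at a TPM of 0 in replicate 1, and 38 counts at a TPM of 242 in replicate 2. Across protein-coding genes the log2 ratio had a Pearson r of 0.114 with GC content and of 0.017 with log10 length; genes are not independent replicates. The median ratio was 0.24 in the GC-richest of 20 bins of genes.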
